A study of Mus musculus with 18 samples.

How the data were processed

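RNA sequencing of mouse spleen was available for 18 libraries from ICR mice aged 10 weeks, in 6 groups of 3. Per the labels, the spleens were frozen in liquid nitrogen, RNA was taken up in Trizol, purified on a column and made into Illumina libraries. The labels name the genome build mm10 and the aligner Bowtie 0.12.2; the gene counter, the annotation and any filter are not given in the sources used here. The deposited values are FPKM (fragments scaled by transcript length and by the mapped total of the library), a unit inferred from the values because the file does not name it. The values have 2 decimals and their totals differ between libraries (coefficient of variation 6.14%), whereas totals weighted by transcript length varied by 1.46%, as values scaled in that way would. For that check, 18763 of the 19326 symbols (97.1%) were matched to the GENCODE M21 annotation. No further scaling was applied before the main test.

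Of the 19326 entries, 418 were listed at 0 in all 18 libraries and 26 had symbols that had been turned into dates, which were kept under that name and never printed. For 3 symbols that stood on 2 lines each, the line with the highest mean kept the name. Absolute depth is not given, since the file holds no counts, and it was not estimated, so no counting interval or detection floor is stated. The smallest steps between low values of 80 genes put the relative depth of the libraries between 0.947 and 1.06 (tolerance 0.15). These genes were kept because their values in all libraries fit multiples of a shared step. The estimate could therefore hardly have shown a large difference in depth. The summed FPKM ran from 666441 to 831448. The labels do not state explicitly that the 3 libraries of a group come from separate animals, so the p-values measure the spread between these libraries. Spearman correlations across genes, which are not independent replicates, were 0.950 to 0.989 within groups and 0.936 to 0.989 between groups, and 0 pairs of libraries were identical. The first principal component held 33.0% of the variance and the second 13.2%.

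Genes with at least 1 FPKM in at least 3 libraries were tested (12969 genes). limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) over all 18 libraries with group as the sole factor, with eBayes using trend and robust (12 residual and 3.38 prior degrees of freedom). Tests were two-sided, Benjamini-Hochberg adjusted within a contrast, with a threshold of 0.05; a gene past it is described as called. The planned contrasts were HS vs control, HS_AOS vs HS, HS_AOSFMT vs HS, HS_conFMT vs HS, HS_AOSFMT vs HS_conFMT, AOS vs control, and the interaction, which is the AOS effect under high fat diet and STZ minus the AOS effect without them. The model, the contrasts, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Contrasts of HS_AOS, HS_AOSFMT and HS_conFMT against control, and of the 4 HS groups together against AOS and control, were added later. So were the covariate fits, the fits with HS 1, HS_AOS 1 and control 1 set aside, and the leave-one-out fits of the lists. Those 3 were not the only libraries apart from their groups on the first principal component. Control 3 (19.4 against -31.5 and -2.66) and HS_conFMT 2 (25.3 against -2.92 and -7.52) were kept.

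Log2 changes are limma coefficients on log2(FPKM + 1) with their standard errors (SE); levels are mean FPKM ± SD over the 3 libraries of a group. In each contrast the text names up to 10 called genes per direction with the largest change among those whose groups did not overlap, leaving out predicted genes and immunoglobulin and T cell receptor segments. Where fewer than 5 genes qualified, the 5 with the smallest unadjusted p per direction are named with values alone. From each gene list described, up to 4 members with the smallest p are named. Any other gene named was chosen after its values were seen.

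Of 33 lists fixed beforehand (561 genes, 553 of them in the file), 31 were tested with camera from limma at a preset correlation of 0.01, adjusted over the 31 lists of a contrast. Each was also tested with a correlation estimated from the data and with fry, and its members were counted as called over all genes and adjusted over the list alone. Over the 6 group contrasts, camera called 81 of 186 list tests, 1 of them also with an estimated correlation, and fry called 8. That 1 was the glucocorticoid list in HS_AOSFMT vs HS. The skeletal muscle list had fewer than 5 tested members. The sex-linked list served to check the samples: Xist had no entry, and the Y-linked gene Ddx3y lay between 26.7 and 47.4 FPKM in all 18 libraries.

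Reversal of the HS changes was measured as the median, over the 200 genes with the smallest p in HS vs control, of the change in each further HS group signed by the HS change. It was set beside 100 simulated draws in which the HS libraries were shared and no group differed from another, HS from control included. The 100 genes with the smallest p among those higher in HS than in control, and the 100 among those lower, were also tested with camera in HS_AOSFMT vs HS_conFMT. That contrast shares no library with HS vs control. Where at least 20 genes were called in HS vs control, the called genes took the place of these sets and of the 200.

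Alternatives were quantile normalization, limma without trend and robust, no filter, a pseudocount of 0.1 in place of 1, fits to the groups of the contrast alone, a block on replicate number, and leaving out each library in turn. Added later were the mean log2 level of the erythroid or of the acinar list as a covariate, and fits without HS 1, HS_AOS 1 and control 1. Replicate numbers were read as pairs where all 3 same-number residual correlations exceeded 0.1, which held for HS_AOS vs HS alone (0.487, 0.287 and 0.372). That contrast called 0 genes unblocked (674 at an unadjusted p under 0.05), 0 with the block over all groups (753) and 1 with the block within its 2 groups (1105). Across all 18 libraries, 8 had their best match in a library with the same number.

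The pipeline was tested on simulated data with known changes in 200 of the 12969 genes and noise independent between genes. In the layout of HS_AOSFMT vs HS, 92% of 100 genes changed by log2 1 and 50% of 100 changed by log2 0.5 were called, with 12 false calls (7.59%). In the layout of HS vs control the shares were 85% and 53%, with 2 false calls (1.42%). A T cell list shifted by log2 0.5 was called in both, and 0 other lists were. The shares of false calls are of all calls, which also include called members of that T cell list. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

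The levels of 3 genes are not reported here, and any list that includes one was tested with all its members that passed the filter.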

Results

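Gene expression was measured by RNA sequencing in the spleen of ICR mice aged 10 weeks, in 18 libraries that form 6 groups of 3. The control group was untreated, and the AOS group received AOS at 10 mg/kg; the labels do not spell out the abbreviation. The HS group was given a high fat diet and streptozotocin (STZ), which damages insulin-producing cells. The remaining groups had the same diet and STZ with AOS (HS_AOS), with a faecal microbiota transplant (FMT) from AOS-treated donors (HS_AOSFMT), or with FMT from control donors (HS_conFMT). The title of the series asks whether FMT from AOS-treated donors rescues the spleen from diet and STZ. Between 12221 and 12898 genes reached 1 FPKM per library, and summed FPKM ran from 666441 to 831448. Relative depth was put at 0.947 to 1.06, by an estimate that could hardly have shown a large difference. Absolute depth is not given and was not estimated, so low values stand here without a counting error. The alpha-globin transcript Hba-a1 was the highest in all 18 libraries, and haemoglobin genes took 12.9% to 35.5% of the summed FPKM.

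High fat diet with STZ against control asks what diet and STZ alone did to the spleen. Plin2 (chromosome 4, 86648386 to 86670060, mm10), which encodes a coat protein of lipid droplets, rose from 23.6 ± 1.70 to 40.1 ± 1.55 FPKM (log2 change 0.74, SE 0.087, adjusted p = 0.00205). Kap (chromosome 6, 133849851 to 133853762), an androgen-regulated transcript best known from kidney, fell from 18.1 ± 4.17 to 0.763 ± 0.785 FPKM (log2 change -3.50, SE 0.28, adjusted p = 2.97e-05). Kap was also listed at 0 in every AOS library, without diet or STZ, so its difference from control is not particular to diet and STZ. Genes of fatty acid oxidation and plasma cell markers were higher in HS as lists, and neutrophil genes were lower, by camera at its preset correlation alone. limma called 2 of 12969 genes, and 830 had an unadjusted p under 0.05. Both calls held without any 1 of the 6 libraries, but the count was 7 without control 2 and 20 without control 3. Fitted to these groups alone, limma called 0 genes (448 unadjusted), and with a pseudocount of 0.1 Kap was no longer called.

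Uncalled genes with the smallest p in this contrast were Acot1, an acyl-CoA thioesterase (7.70 ± 4.98 in HS, 1.66 ± 0.232 in control), Cyp1b1 (19.3 ± 4.10 and 8.89 ± 2.20), Adamtsl4 (2.72 ± 0.441 and 1.53 ± 0.240). Angptl4, a PPAR target that inhibits lipoprotein lipase, was also among them (16.5 ± 4.11 and 8.08 ± 1.42). On the lower side they were Oxct1, an enzyme of ketone body use (24.8 ± 1.98 and 33.9 ± 1.60, adjusted p = 0.0544), and the sperm-specific genes Tnp1 (0.173 ± 0.15 and 16.1 ± 20.3), Prm1 (0.563 ± 0.746 and 34.5 ± 44.3) and Prm2 (0.147 ± 0.145 and 21.6 ± 28.9). The sperm genes were highest in control 2, where Prm1 reached 85.6 FPKM against 11.3 in control 1 and 6.56 in control 3. As a list, fatty acid oxidation and PPAR target genes rose by camera (median log2 change 0.15, 13 of 20 positive, adjusted p = 9.28e-07; adjusted p = 0.373 with an estimated correlation). In that list 1 member was called over all genes and 8 adjusted over the list alone, among them Plin2, Acot1, Angptl4 and Cpt1a, which gates fatty acid entry into mitochondria (37.6 ± 8.82 and 23.9 ± 1.2). The list median was 0.093 without HS 1.

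Plasma cell markers rose as a list (median 0.48, 12 of 12 positive, adjusted p = 1.28e-09; adjusted p = 0.322 with an estimated correlation), with 0 members called over all genes by limma (12 tested) and 6 adjusted over the list alone. Among them were Jchain, the joining chain of IgM and IgA (836 ± 250 and 489 ± 234), and Derl3 (21.3 ± 5.28 and 10.8 ± 6.37). The median was 0.31 without HS 1. Unfolded protein response genes rose (median 0.29, 14 of 16 positive, adjusted p = 8.52e-08; adjusted p = 0.322 with an estimated correlation), with Herpud1 at 85.5 ± 5.72 and 61.5 ± 12.8. Without control 1 the median was 0.19. T cell markers rose (median 0.28, 17 of 17 positive, adjusted p = 1.82e-05; adjusted p = 0.508 with an estimated correlation). Without control 1 their median was 0.034 (adjusted p = 0.305). Neutrophil and granule genes fell (median -1.03, 0 of 18 positive, adjusted p = 8.52e-08; adjusted p = 0.450 with an estimated correlation). Mmp9 stood at 6.42 ± 2.33 and 20 ± 18.8. That list rested on control 1, which was rich in neutrophil transcripts. Its median was -0.21 without control 1 (adjusted p = 0.674), -2.10 without control 3 and -0.42 with HS 1, HS_AOS 1 and control 1 set aside (adjusted p = 0.0685).

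Lists of pancreatic acinar, adipocyte and cholesterol synthesis genes also differed. Pancreatic acinar genes rose in HS as a list (median 3.96, 25 of 26 positive, adjusted p = 1.52e-18; adjusted p = 0.373 with an estimated correlation). limma called 0 of its 26 members, over all genes or adjusted over the list alone. Try5, a trypsinogen, stood at 700 ± 850 in HS and 36.7 ± 51.2 in control, and the list took 3.33% of the summed FPKM in HS 1 against 0.371% and 0.536% in HS 2 and HS 3. Adipocyte genes fell (median -1.14, 0 of 12 positive, adjusted p = 2.56e-05; adjusted p = 0.450 with an estimated correlation). Car3 stood at 15.2 ± 13.3 and 66.1 ± 45.5. The median was -0.72 without control 2, and the call ended with the acinar level as a covariate (median -0.47, adjusted p = 0.0576). Cholesterol synthesis genes fell (median -0.15, 3 of 19 positive, adjusted p = 0.000998; adjusted p = 0.450 with an estimated correlation). Mvk, mevalonate kinase, stood at 4.50 ± 0.318 and 4.86 ± 0.476 and was not called (adjusted p = 0.965). That call ended without HS 1 (median -0.063, adjusted p = 0.164) and with 3 libraries set aside (median -0.086, adjusted p = 0.0883). Camera called 6 further lists, 5 up and 1 down (medians -1.03 to 0.31), and none of the 14 lists was called with an estimated correlation.

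**Figure D1:**
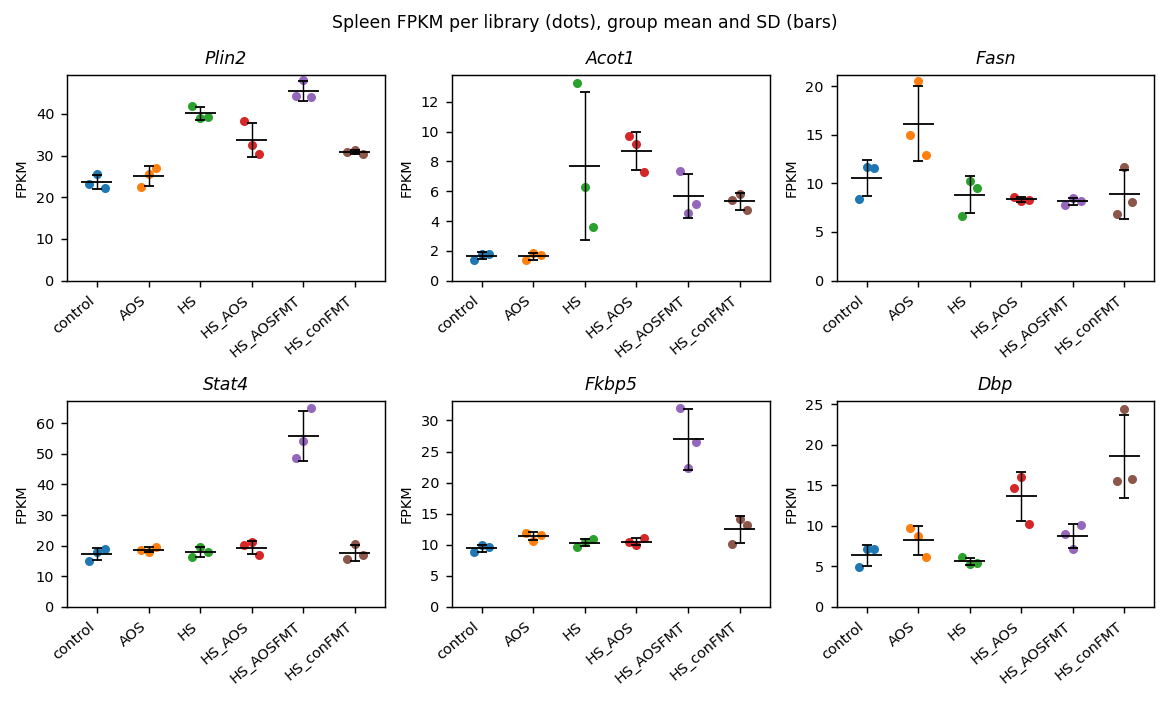
FPKM of 6 genes (vertical axes, from 0) in the 6 groups (horizontal axes), with a dot per library, a line at the mean and bars of 1 SD over 3 libraries. Plin2 and Acot1 lay higher in every HS group than in control and AOS, Stat4 and Fkbp5 were highest in HS_AOSFMT, and Dbp was highest in HS_conFMT.

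AOS given with the diet and STZ was compared with HS to ask whether AOS itself changed the spleen under that treatment. No single gene passed the test. Heat shock and unfolded protein response genes fell together as lists, and circadian clock genes rose, all by camera at its preset correlation and not with an estimated one. The chaperonin Hspe1 stood at 164 ± 15.1 FPKM in HS_AOS and 284 ± 81.4 in HS, and the clock output gene Dbp at 13.7 ± 3.02 and 5.63 ± 0.461. limma called 0 of 12969 genes (smallest adjusted p 0.390), and 674 had an unadjusted p under 0.05. With limma 0 were also called with a block on replicate number over all groups (753 unadjusted). Within these 2 groups 1 gene was called, with or without the block: Zfp979, a zinc finger gene, at 0.05 ± 0.0346 in HS_AOS and 8.01 ± 2.14 in HS. Without HS 1 the count was 3, Hspe1 and the mitochondrial ribosome gene Mrps6 (19.2 ± 1.85 and 34.2 ± 9.34) among them; with 3 libraries set aside it was 5.

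The heat shock list had a median log2 change of -0.77 in HS_AOS (0 of 12 positive, adjusted p = 4.80e-18; adjusted p = 0.192 with an estimated correlation). limma called 0 members over all genes (12 tested) and 7 adjusted over the list alone. Hspb1 stood at 16.2 ± 7.04 and 40.8 ± 15.7, and the median was -1.15 without HS 1. Unfolded protein response genes fell (median -0.36, 0 of 16 positive, adjusted p = 4.80e-18; adjusted p = 0.0598 with an estimated correlation). Of its members 9 passed adjusted over the list alone, including the endoplasmic reticulum chaperones Hsp90b1 (272 ± 19.9 and 392 ± 6.89) and Hspa5 (215 ± 4.65 and 286 ± 27.1). Circadian clock genes rose (median 0.17, 12 of 14 positive, adjusted p = 3.00e-05; adjusted p = 0.563 with an estimated correlation). Of these 6 passed adjusted over the list alone, among them Dbp and Nr1d1, a repressor in the clock (7.57 ± 1.29 and 3.61 ± 0.283). Without HS 2 the median was 0.26. Clock genes vary over the day and the hour of collection is not given, so for them hour and group cannot be told apart in any contrast. Other uncalled genes with the smallest p were Ccdc62 (2.69 ± 0.173 and 1.43 ± 0.175), Tctn1 (4.68 ± 0.178 and 2.77 ± 0.163), the chemokine receptor gene Cxcr6 (7.08 ± 1.19 and 4.58 ± 0.385), Zfp984 (1.44 ± 0.327 and 6.59 ± 2.18) and Gpx3 (64.1 ± 12.6 and 117 ± 32.9).

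Neutrophil and granule genes fell as a list in HS_AOS (median -1.09, 0 of 18 positive, adjusted p = 9.18e-11; adjusted p = 0.563 with an estimated correlation). Lcn2 stood at 34.4 ± 7.68 and 94.5 ± 39.7, and the median was -0.71 without HS 1. Plasma cell markers fell (median -0.30, 2 of 12 positive, adjusted p = 2.99e-05; adjusted p = 0.578 with an estimated correlation). The plasma cell call ended without HS 1 (median -0.080, adjusted p = 0.0711). Xbp1, a driver of secretory cell fate, stood at 57.5 ± 4.03 and 72.6 ± 11.6. Acinar genes fell (median -0.82, 0 of 26 positive, adjusted p = 0.000368; adjusted p = 0.784 with an estimated correlation). The list took 3.70% of the summed FPKM in HS_AOS 1 and 3.33% in HS 1. Its median was 0.15 without HS 1, 0.47 without HS_AOS 3 and -0.69 without HS_AOS 2 (adjusted p = 0.450, 0.449 and 0.0577), and -1.41 and -2.30 without HS 2 and HS_AOS 1. Camera called 7 further lists, 2 up and 5 down (medians -0.30 to 0.19), and none of the 13 lists was called with an estimated correlation.

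FMT from AOS-treated donors was compared with HS to ask what that transplant changed in the spleen under diet and STZ. It was the treatment with the widest change against HS: 1048 genes rose and 149 fell. Stat4 (chromosome 1, 51987148 to 52107189), which relays interleukin 12 signals in T and NK cells, rose from 18 ± 1.63 to 55.9 ± 8.17 FPKM (log2 change 1.58, SE 0.12, adjusted p = 9.21e-06). The steroid receptor co-chaperone gene Fkbp5 (chromosome 17, 28399094 to 28517527) rose from 10.4 ± 0.599 to 27.0 ± 4.86 (log2 change 1.29, SE 0.12, adjusted p = 5.29e-05), and glucocorticoid responsive genes rose with it. T cell markers and clock genes rose as lists, whereas erythroid genes and pancreatic acinar genes fell, by camera for these 4 at its preset correlation and not with an estimated one.

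Beside Stat4 and Fkbp5, the 10 largest rises included the small heat shock gene Hspb1 (40.8 ± 15.7 to 136 ± 15.4; log2 change 1.79), the feedback inhibitor of EGF receptor Errfi1 (9.64 ± 2.35 to 33.5 ± 6.29), and B3gnt7 (2.64 ± 1.05 to 10.5 ± 0.453). The cAMP-responsive regulator Crem (7.65 ± 1.77 to 26.1 ± 2.91; log2 change 1.66), the arginase Arg2 (3.74 ± 0.853 to 12.1 ± 1.41; log2 change 1.47), Rundc3b (1.03 ± 0.122 to 4.42 ± 0.0503) and Chst10 (9.01 ± 2.14 to 23.0 ± 1.77) rose as well. The 10 largest falls were all in the list of pancreatic acinar genes, transcripts typical of another tissue that took 3.33%, 0.371% and 0.536% of the summed FPKM in HS 1, 2 and 3: Ctrb1, Try5, Cela3b, Cela2a, Clps, Pnlip, Prss2, Sycn, Try4 and Rnase1, with log2 changes of -8.56 to -6.93. Ctrb1, chymotrypsinogen B, fell from 2089 ± 2505 to 3.50 ± 4.15 FPKM (adjusted p = 0.0240). Leaving out HS 1, HS 3 or HS_AOSFMT 1 ended the call of Errfi1 (adjusted p 0.0513 to 0.0719). Ctrb1, Try5 and Cela3b lost their calls without HS 1, HS 3 or any HS_AOSFMT library (0.0522 to 0.102), and the other 7 acinar genes without any 1 of the 6 libraries (0.0506 to 0.134). The other 8 rises named here held in each of these fits.

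Glucocorticoid responsive genes rose (median 0.84, 13 of 13 positive, adjusted p = 3.70e-07), and this was the list that camera also called with an estimated correlation (adjusted p = 0.0387). Of its members 9 were called over all genes and 11 adjusted over the list alone. Beside Fkbp5 they included Zbtb16 (0.303 ± 0.0231 to 1.78 ± 0.222) and the metallothionein gene Mt1 (95.7 ± 18.3 to 228 ± 26.7), which stayed called without any 1 library. Pik3ip1 also rose (12.3 ± 3.96 to 24.4 ± 4.14), but its call ended without HS 1, HS 3, HS_AOSFMT 1 or HS_AOSFMT 3 (adjusted p 0.0513 to 0.0661). T cell markers rose (median 0.46, 17 of 17 positive, adjusted p = 0.000176; adjusted p = 0.769 with an estimated correlation). Of its genes 5 were called over all genes and 7 adjusted over the list alone. The interleukin 7 receptor gene Il7r rose from 16.6 ± 3.84 to 39.4 ± 4.32. Lat, an adaptor of the T cell receptor, rose from 65.1 ± 7.37 to 104 ± 10.9, a call that ended without HS_AOSFMT 1 or HS_AOSFMT 3 (adjusted p 0.0503 and 0.0533). With the acinar level as a covariate the T cell list was not called (median 0.14, adjusted p = 0.114). Circadian clock genes rose (median 0.31, 14 of 14 positive, adjusted p = 0.000919; adjusted p = 0.769 with an estimated correlation). Here 5 were called over all genes and 8 adjusted over the list alone, such as Per2 (2.38 ± 0.343 to 4.68 ± 0.164) and Nr1d1 (3.61 ± 0.283 to 7.77 ± 1.70), which lost its call without HS_AOSFMT 3 (adjusted p = 0.0550).

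Erythroid genes fell (median -0.68, 0 of 24 positive, adjusted p = 4.25e-12; adjusted p = 0.535 with an estimated correlation). In this list 1 was called over all genes and 5 adjusted over the list alone. Alas2, the first enzyme of haem synthesis in red cells, fell from 641 ± 15.4 to 290 ± 56.8, a call lost without any 1 of the 6 libraries (highest adjusted p 0.151). Haemoglobin genes took 12.9% to 17.6% of the summed FPKM in HS_AOSFMT and 26.8% to 29.1% in HS. Cell division genes fell (median -0.38, 0 of 24 positive, adjusted p = 1.18e-08; adjusted p = 0.769 with an estimated correlation). limma called 0 of the 24 members, over all genes or adjusted over the list alone, and Ccnb2 stood at 38.9 ± 9.09 and 66.6 ± 14.4. That median was -0.24 without HS 1, and it turned to 0.22 with the erythroid level as a covariate (adjusted p = 0.0103) and to 0.052 with the acinar level (adjusted p = 0.577). Cholesterol synthesis genes fell by camera (adjusted p = 0.000348; adjusted p = 0.535 with an estimated correlation), with a median of -0.036 over 19 genes that went both ways. Over all genes 3 were called, and the same 3 adjusted over the list alone, among them Mvk (4.50 ± 0.318 to 3.07 ± 0.476; adjusted p = 0.0340). The median was -0.12, -0.020 and 0.021 without HS 1, HS 2 and HS 3. Mvk lost its call without any 1 of the 6 libraries (highest adjusted p 0.110).

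Acinar genes fell as a list (median -6.71, 0 of 26 positive, adjusted p = 2.35e-26; adjusted p = 0.451 with an estimated correlation). Of them 20 were called over all genes and 25 adjusted over the list alone. They took 0.00343% to 0.0117% of the summed FPKM in HS_AOSFMT and 0.371% to 3.33% in HS. Adipocyte genes rose (median 1.26, 12 of 12 positive, adjusted p = 0.0118; adjusted p = 0.940 with an estimated correlation). Their call ended without HS 1 or HS 3 (adjusted p 0.0515 and 0.0630) and with the erythroid or acinar level as a covariate (medians 0.62 and 0.45, adjusted p 0.158 and 0.577). Scd1, a fatty acid desaturase, rose from 67.6 ± 8.65 to 134 ± 9.34 and was the 1 member called, both over all genes and adjusted over the list alone, though not without HS 1, HS 3 or any HS_AOSFMT library (highest adjusted p 0.102). Plasma cell markers fell (median -0.33, 4 of 12 positive, adjusted p = 0.00386; adjusted p = 0.769 with an estimated correlation), but not without HS 1 (median -0.12, adjusted p = 0.0605) or with 3 libraries set aside (median -0.12, adjusted p = 0.0599). Sdc1, the surface marker CD138, fell from 6.65 ± 2.10 to 3.69 ± 0.204, a call lost without HS 1 or any HS_AOSFMT library (highest adjusted p 0.140). Camera called 4 further lists, 1 up and 3 down (medians -0.32 to 0.15).

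In this contrast limma called 1197 of 12969 genes, 3631 had an unadjusted p under 0.05, and the median change of all genes was 0.10. The up-to-down split was 87.6% up as deposited; under quantile normalization, which brought the median to 0.026, it was 71.0% up of 794 calls, 692 of them shared. The count was 264, 751 and 376 without HS 1, HS 2 and HS 3, and 203, 531 and 299 without HS_AOSFMT 1, 2 and 3, and 153 genes were called in every such fit. It was 388 with 3 libraries set aside, 83 with the erythroid level as a covariate (352 with the beta-globin genes left out of that level) and 18 with the acinar level.

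**Figure D2:**
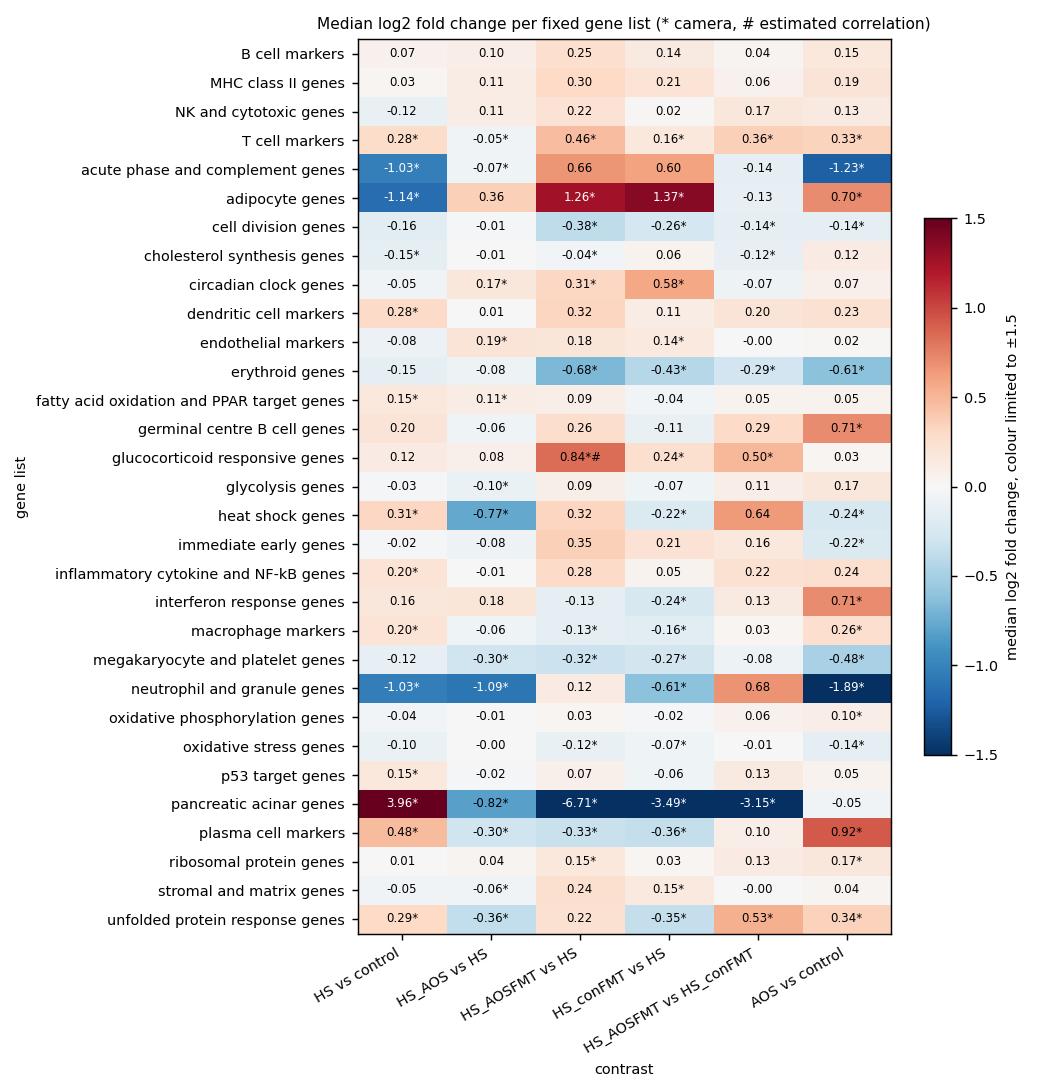
Median log2 change of each of 31 gene lists (vertical axis) in the 6 group contrasts (horizontal axis); colour is limited to 1.5 in either direction, a star marks a camera call at the preset correlation and a hash 1 with an estimated correlation. The hash stands at the glucocorticoid list in HS_AOSFMT vs HS (median 0.84), and the acinar list runs from 3.96 in HS vs control to -6.71 in HS_AOSFMT vs HS.

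FMT from control donors was compared with HS as the transplant without donor treatment. A single gene was called: Dbp (chromosome 7, 45705088 to 45710203), a clock output gene, rose from 5.63 ± 0.461 to 18.6 ± 5.09 FPKM (log2 change 1.53, SE 0.21, adjusted p = 0.0232), and further clock genes rose with it as a list. Unfolded protein response genes fell as a list, and adipocyte genes rose, all 3 by camera at its preset correlation and not with an estimated one. The hour of collection is not given, so for the clock genes it cannot be told apart from the groups. limma called 1 of 12969 genes, and 819 had an unadjusted p under 0.05. The call of Dbp ended without any 1 of the 6 libraries (adjusted p 0.0576 to 0.213), where the count was 0, and in fits to these groups alone and with a replicate block. limma called 0 genes with the erythroid covariate (937 unadjusted) and with 3 libraries set aside (896 unadjusted), and Dbp was not the 1 gene called with the acinar covariate. Quantile normalization gave 4 genes, limma without trend and robust 4, and no filter 2.

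Circadian clock genes rose in HS_conFMT (median 0.58, 13 of 14 positive, adjusted p = 1.94e-13; adjusted p = 0.251 with an estimated correlation). Dbp was the 1 called over all genes, and 9 passed adjusted over the list alone. Nr1d1 stood at 9.50 ± 1.06 and 3.61 ± 0.283, and the Dbp relatives Hlf and Tef at 1.37 ± 0.166 and 0.457 ± 0.0777, and at 17.2 ± 1.78 and 9.76 ± 0.329. Unfolded protein response genes fell (median -0.35, 2 of 16 positive, adjusted p = 4.47e-09; adjusted p = 0.274 with an estimated correlation), 6 of them adjusted over the list alone. Pdia6, a disulfide isomerase, stood at 75.2 ± 13.6 and 104 ± 4.61, and the median was -0.16 without HS_conFMT 1. Glucocorticoid responsive genes rose (median 0.24, 10 of 13 positive, adjusted p = 0.00320; adjusted p = 0.289 with an estimated correlation), 4 of them adjusted over the list alone. Among the 4 was the growth regulator Ddit4 (60.6 ± 11 and 35.9 ± 5.99). Other uncalled genes with the smallest p were Sh2d6 (1.04 ± 0.0231 and 0.300 ± 0.135), the lysosomal glucosidase Gaa (9.75 ± 0.336 and 13.4 ± 0.243) and Swt1 (11.1 ± 0.887 and 17.2 ± 2.45). They also included the DNA repair gene Fanca (4.82 ± 0.552 and 7.25 ± 1.04), Cars (14.9 ± 1.05 and 19.7 ± 1.02) and Ccnb1ip1 (6.64 ± 1.10 and 10.9 ± 1.98).

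Adipocyte genes rose in HS_conFMT (median 1.37, 12 of 12 positive, adjusted p = 3.02e-08; adjusted p = 0.470 with an estimated correlation), 1 of them adjusted over the list alone. That 1 was Thrsp, a regulator of fat synthesis, at 4.36 ± 1.82 and 0.793 ± 0.437. The median was 0.87 without HS_conFMT 2. Erythroid genes fell (median -0.43, 2 of 24 positive, adjusted p = 2.39e-07; adjusted p = 0.641 with an estimated correlation), with a median of -0.79 without HS_conFMT 1 and 0.037 without HS_conFMT 2 (adjusted p = 0.820). Acinar genes fell (median -3.49, 1 of 26 positive, adjusted p = 2.84e-16; adjusted p = 0.470 with an estimated correlation), with Try5 at 41.7 ± 63.7 and 700 ± 850. Plasma cell markers fell (median -0.36, 2 of 12 positive, adjusted p = 2.91e-05; adjusted p = 0.516 with an estimated correlation), with a median of -0.17 without HS 1. Camera called 10 further lists, 3 up and 7 down (medians -0.61 to 0.16), and none of the 17 lists was called with an estimated correlation.

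The donor contrast, HS_AOSFMT vs HS_conFMT, asks what the AOS treatment of the donor added to a transplant. Stat4 rose from 17.7 ± 2.66 to 55.9 ± 8.17 FPKM (log2 change 1.61, SE 0.12, adjusted p = 1.40e-05). Arg2 (chromosome 12, 79130777 to 79156301) rose from 2.13 ± 0.323 to 12.1 ± 1.41 (log2 change 2.06, SE 0.20, adjusted p = 6.34e-05). The same HS_AOSFMT libraries stand in HS_AOSFMT vs HS, so these rises are not an independent repeat of those against HS. Glucocorticoid responsive and unfolded protein response genes rose as lists, and cholesterol synthesis genes fell, by camera at its preset correlation and not with an estimated one. limma called 759 of 12969 genes, 624 up and 135 down, and 2951 had an unadjusted p under 0.05. The split was 82.2% up as deposited and 64.5% up of 704 calls under quantile normalization, with medians of all genes of 0.062 and 0.013. The count was 257, 236 and 271 without HS_AOSFMT 1, 2 and 3, and 199, 1201 and 319 without HS_conFMT 1, 2 and 3, with 144 genes called in every such fit. HS_conFMT 2 lay among HS_AOSFMT on the first principal component (25.3 against 21.8 to 30.8), unlike HS_conFMT 1 and 3 (-2.92 and -7.52). Its haemoglobin share (14.7%) was also within that of HS_AOSFMT (12.9% to 17.6%). In the fit to these 2 groups alone the spread comes from these libraries only. It was 176 in a fit to these groups alone, 1184 with the erythroid level as a covariate and 335 with the acinar level.

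Other rises in HS_AOSFMT over HS_conFMT were Hspb1 (35.1 ± 4.92 to 136 ± 15.4), Crem (7.61 ± 1.14 to 26.1 ± 2.91), the metallothionein Mt2 (60.2 ± 12.9 to 166 ± 35.3), the inflammatory cytokine Il1b (11.7 ± 2.60 to 31.6 ± 6.55). Rises were also seen in the inhibitory receptor Lilrb4a (9.87 ± 6.65 to 29.5 ± 9.21), Zfp984 (3.55 ± 2.11 to 10.8 ± 2.91), Slc37a2 (3.64 ± 1.99 to 10.2 ± 2.27) and Dmkn (1.18 ± 0.257 to 4.75 ± 1.97). Hspb1, Crem, Mt2 and Il1b held without any 1 library. Falls were Gdpd3 (62.3 ± 51.2 to 0.367 ± 0.117), Mup19 (10.2 ± 7.16 to 1.05 ± 1.14), Irgc1 (2.46 ± 0.942 to 0.470 ± 0.05), and Id4 (4.75 ± 0.530 to 1.70 ± 0.390). Further falls were Dbp (18.6 ± 5.09 to 8.73 ± 1.52), Rpl37rt (39.3 ± 1.65 to 19.7 ± 5.20) and Sspn (4.41 ± 1.84 to 1.69 ± 0.342). So were the cold-inducible RNA binding gene Rbm3 (373 ± 26.5 to 192 ± 19.4), the plasma cell receptor Tnfrsf17 (3.24 ± 0.690 to 1.21 ± 0.378) and Fgfr4 (3.70 ± 0.320 to 1.62 ± 0.629). Of the falls, Id4 and Rbm3 held without any 1 library. Dmkn and Tnfrsf17 lost their calls without any 1 of the 6 libraries (highest adjusted p 0.165), and Lilrb4a and Irgc1 in all fits but the one without HS_conFMT 2 (0.173). That of Gdpd3 ended without any HS_AOSFMT library or HS_conFMT 3 (0.0737), and that of Zfp984 without HS_AOSFMT 1, HS_AOSFMT 3, HS_conFMT 2 or HS_conFMT 3 (0.102). Fgfr4 and Rpl37rt lost theirs without HS_AOSFMT 2, HS_AOSFMT 3, HS_conFMT 1 or HS_conFMT 3 (0.0855), and Mup19 without HS_AOSFMT 2, HS_AOSFMT 3 or HS_conFMT 3 (0.107). Leaving out HS_AOSFMT 3 or HS_conFMT 1 did so for Slc37a2 (0.0704), and leaving out HS_AOSFMT 2 for Dbp and Sspn (0.0642).

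Glucocorticoid responsive genes rose in the donor contrast (median 0.50, 12 of 13 positive, adjusted p = 0.000422; adjusted p = 0.259 with an estimated correlation). The 4 called over all genes were also called adjusted over the list alone: Fkbp5 (12.5 ± 2.16 to 27.0 ± 4.86), Zbtb16 (0.547 ± 0.202 to 1.78 ± 0.222), Mt1 (102 ± 17.2 to 228 ± 26.7) and Mt2. Those 4 held without any 1 library, while the median was 0.33 without HS_conFMT 1. In the same contrast unfolded protein response genes rose (median 0.53, 13 of 16 positive, adjusted p = 0.000591; adjusted p = 0.973 with an estimated correlation). Here 9 were called over all genes and 10 adjusted over the list alone. The chaperones Hspa5 (224 ± 36.9 to 382 ± 24.0), Hsp90b1 (281 ± 59.9 to 500 ± 50.7) and Pdia6 (75.2 ± 13.6 to 136 ± 12) held without any 1 library. T cell markers rose (median 0.36, 17 of 17 positive, adjusted p = 0.00573; adjusted p = 0.973 with an estimated correlation), with 1 called over all genes and 4 adjusted over the list alone. Il7r rose from 23.9 ± 3.93 to 39.4 ± 4.32, a call lost in all fits but the one without HS_conFMT 2 (highest adjusted p 0.158). The list lost its call without HS_AOSFMT 3 (median 0.27, adjusted p = 0.0725) and with the acinar covariate (median 0.22, adjusted p = 0.0937).

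Cholesterol synthesis genes fell in HS_AOSFMT against HS_conFMT (median -0.12, 3 of 19 positive, adjusted p = 0.000258; adjusted p = 0.680 with an estimated correlation). Over all genes 2 were called, and the same 2 adjusted over the list alone, among them Mvk (4.86 ± 0.382 to 3.07 ± 0.476). Mvk lost its call without HS_AOSFMT 2, HS_AOSFMT 3 or HS_conFMT 1 (highest adjusted p 0.0846), and the median was -0.075 without HS_conFMT 2. Erythroid genes fell (median -0.29, 5 of 24 positive, adjusted p = 0.000591; adjusted p = 0.973 with an estimated correlation). Hba-a1 stood at 64437 ± 12877 and 120993 ± 61151. That median was 0.015 without HS_conFMT 1 (adjusted p = 0.677), -0.71 and -0.19 without HS_conFMT 2 and 3, -0.18, -0.53 and -0.17 without HS_AOSFMT 1, 2 and 3, and -0.081 with the acinar covariate (adjusted p = 0.0544). Acinar genes fell (median -3.15, 0 of 26 positive, adjusted p = 1.63e-09; adjusted p = 0.973 with an estimated correlation), with a median of -1.65 without HS_conFMT 3. Camera called 1 further list, the cell division genes (median -0.14), and none of the 7 lists was called with an estimated correlation.

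AOS against control asks what AOS did in mice without diet or STZ. Kap was listed at 0 in all 3 AOS libraries and stood at 18.1 ± 4.17 FPKM in control (adjusted p = 2.00e-06), the 1 gene called. Plasma cell markers, unfolded protein response genes and interferon response genes rose as lists, and neutrophil and erythroid genes fell, by camera at its preset correlation and not with an estimated one. The epithelial adhesion gene Epcam stood at 5.88 ± 1.12 and 2.20 ± 0.541, Nr1d1 at 4.97 ± 1.59 and 1.91 ± 0.269, and the cargo receptor Lman1 at 29.6 ± 4.40 and 18.8 ± 0.918, all uncalled. limma called 1 of 12969 genes, and 1471 had an unadjusted p under 0.05. The count was 3 without AOS 2, 2 without AOS 3, 12 without control 2 and 49 without control 3. It was 2 without trend and robust, 7 without a filter and 2 with a pseudocount of 0.1.

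Further uncalled genes with the smallest p in AOS vs control were Slc35f2 (2.46 ± 0.0839 and 1.54 ± 0.0757) and Manea (14.7 ± 0.897 and 10.3 ± 0.535). They also included the sperm genes Tnp1 (0.0867 ± 0.15 and 16.1 ± 20.3) and Prm1 (0.380 ± 0.329 and 34.5 ± 44.3), Timp3 (24.3 ± 2.51 and 35.8 ± 3.74) and Sord (14.4 ± 1.33 and 21 ± 2.77). Plasma cell markers rose (median 0.92, 12 of 12 positive, adjusted p = 3.60e-14; adjusted p = 0.359 with an estimated correlation), all 12 of them adjusted over the list alone. Derl3 stood at 29.3 ± 7.03 and 10.8 ± 6.37 and Xbp1 at 87.7 ± 14.0 and 55.3 ± 6.20. Unfolded protein response genes rose (median 0.34, 12 of 16 positive, adjusted p = 0.000215; adjusted p = 0.531 with an estimated correlation), 9 of them adjusted over the list alone. Hsp90b1 stood at 531 ± 82.6 and 305 ± 50.8, and the median was 0.18 without control 1. Interferon response genes rose (median 0.71, 19 of 20 positive, adjusted p = 2.14e-06; adjusted p = 0.531 with an estimated correlation), 3 of them adjusted over the list alone. The nucleic acid sensor Zbp1 stood at 58.5 ± 27.2 and 24.2 ± 0.294. That median was 1.16 without AOS 2 and 0.39 without AOS 3.

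Neutrophil and granule genes fell in AOS (median -1.89, 0 of 18 positive, adjusted p = 3.65e-18; adjusted p = 0.478 with an estimated correlation), all 18 of them adjusted over the list alone. S100a8 stood at 297 ± 143 and 2248 ± 2569, and the median was -0.89 without control 1 and -2.97 without control 3. T cell markers rose (median 0.33, 17 of 17 positive, adjusted p = 1.46e-05; adjusted p = 0.550 with an estimated correlation), 1 of them adjusted over the list alone, the costimulatory receptor Cd28 (15.7 ± 2.41 and 9.34 ± 2.57). Their median was 0.12 without control 1 and 0.50 without control 3. Germinal centre B cell genes rose (median 0.71, 10 of 10 positive, adjusted p = 0.000388; adjusted p = 0.531 with an estimated correlation). Mybl1 stood at 10.6 ± 1.01 and 5.43 ± 2.61. The list was not called without control 3 (median 0.49, adjusted p = 0.102). Erythroid genes fell (median -0.61, 1 of 24 positive, adjusted p = 1.52e-09; adjusted p = 0.531 with an estimated correlation). The transferrin receptor Tfrc stood at 81.5 ± 10.8 and 135 ± 40. Ribosomal protein genes rose (median 0.17, 29 of 30 positive, adjusted p = 8.21e-08; adjusted p = 0.531 with an estimated correlation), 1 of them adjusted over the list alone, Rpl11 (1622 ± 91.2 and 1311 ± 48.7). Camera called 9 further lists, 3 up and 6 down (medians -1.23 to 0.70), and none of the 17 lists was called with an estimated correlation.

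The interaction asks whether AOS acted differently with and without diet and STZ. Kap was the 1 gene called by limma (adjusted p = 0.00195), since it differed between AOS and control but was near 0 in both HS (0.763 ± 0.785) and HS_AOS (0.1 ± 0.0866); 774 genes had an unadjusted p under 0.05. The count was 4 without AOS 2 and 8 without control 2, and 0 with a pseudocount of 0.1. Over the 6 group contrasts, B cell markers (medians 0.038 to 0.25), MHC class II genes (0.028 to 0.30) and NK and cytotoxic genes (-0.12 to 0.22) were not called in any, with smallest adjusted p of 0.0569, 0.0675 and 0.0528.

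The remaining HS groups were also set against control, a comparison added after the data were seen. In HS_AOS 6 genes rose and 6 fell. Nr1d1 (1.91 ± 0.269 to 7.57 ± 1.29), Acot1 (1.66 ± 0.232 to 8.73 ± 1.28), Cpt1a (23.9 ± 1.2 to 43.1 ± 5.37), Klf10 (9.87 ± 0.154 to 14.2 ± 0.327), Cyp1b1 (8.89 ± 2.20 to 20.7 ± 2.50) and Plin2 (23.6 ± 1.70 to 33.8 ± 4.05) rose. Kap, Oxct1 (33.9 ± 1.60 to 23.8 ± 0.270), Tnp1 (listed at 0 in HS_AOS), Prm1 and the smooth muscle genes Tagln (88.2 ± 4.37 to 56.0 ± 10.2) and Acta2 (57.9 ± 12.7 to 33.8 ± 5.43) fell. In HS_conFMT 5 were called, with Nr1d1 (to 9.50 ± 1.06), Dbp (6.39 ± 1.30 to 18.6 ± 5.09) and Ddit4 (25.4 ± 7.95 to 60.6 ± 11) up and Kap and Tnp1 (listed at 0 in HS_conFMT) down. In HS_AOSFMT 1255 rose and 303 fell, with Stat4 (17.3 ± 2.02 in control, log2 change 1.63, adjusted p = 3.73e-06), Il7r (14.7 ± 3.82 in control, log2 change 1.38) and Plin2 (to 45.5 ± 2.30, log2 change 0.92) among the rises. In HS_AOS, Kap and Nr1d1 were called without any 1 library. The other 10 lost their calls in 3 to 5 of the 6 fits (highest adjusted p 0.106 to 0.318), with HS_AOS 1, 2 or 3 or control 1 or 2 left out. In HS_conFMT, Kap and Nr1d1 again held. Dbp and Ddit4 lost their calls without HS_conFMT 2, HS_conFMT 3 or control 1, and Tnp1 also without HS_conFMT 1 (highest adjusted p 0.167 to 0.182). In HS_AOSFMT 351 of the 1558 were called in every such fit, Stat4, Il7r and Plin2 among them. Far fewer than 1558 were called when HS_AOSFMT and control were fitted alone, or with the erythroid level as a covariate. Those counts are given with the dependence on the processing. limma gave 12, 5 and 1558 calls, with 1016, 1521 and 4133 genes at an unadjusted p under 0.05. Without HS_AOS 1, 2 and 3 the count of 12 was 3, 2 and 9, and without control 1, 2 and 3 it was 6, 6 and 126. The 5 calls were 9, 2 and 2 without HS_conFMT 1, 2 and 3, and 2, 11 and 110 without the controls in turn; the 1558 were 579, 990 and 448 without HS_AOSFMT 1, 2 and 3, and 482, 933 and 3381 without the controls in turn.

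Whether the treatments moved the spleen back towards control was measured on the 200 genes with the smallest p in HS vs control. Of these, 78.0% moved towards control in HS_AOS, 66.5% in HS_AOSFMT and 82.5% in HS_conFMT, with signed medians of -0.12, -0.15 and -0.13. Because the HS libraries stand in both contrasts, draws in which no group differed gave medians of -0.19, -0.18 and -0.19. Each measured value lay inside the central range of its 100 draws, without the outermost draws at either end (-0.45 to -0.016, -0.45 to 0.0059 and -0.41 to 0.0055). HS did not differ from control in these draws either. They therefore cannot show what a real HS change without reversal would give, and reversal was neither shown nor excluded. Of the called genes, Plin2 and Kap, 0 were called in the opposite direction by limma in HS_AOS vs HS, HS_AOSFMT vs HS or HS_conFMT vs HS, where 674, 3631 and 819 genes had an unadjusted p under 0.05. Plin2 stood at 40.1 ± 1.55 in HS, 33.8 ± 4.05 in HS_AOS, 45.5 ± 2.30 in HS_AOSFMT and 30.8 ± 0.427 in HS_conFMT. In the donor contrast, which shares no library with HS vs control, the 100 genes of smallest p higher in HS had a median of 0.12 (camera p from genes as a set 0.363, and 0.778 with an estimated correlation). The 100 of smallest p lower in HS had one of 0.055 (0.938, and 0.968 with an estimated correlation), beside 0.062 for all genes. The signed median in HS_AOS was -0.29, -0.19 and 0.082 without HS 1, HS 2 and control 3. In HS_AOSFMT it was -0.23, -0.26 and -0.091 without HS 2, control 1 and control 2, and in HS_conFMT -0.23 and -0.033 without HS 1 and control 3. The set higher in HS was called higher in the donor contrast without HS 1 (median 0.27, camera p from genes as a set 1.23e-10), HS_AOSFMT 1 (0.12, 0.0332) or HS_conFMT 2 (0.23, 0.00342). The set lower in HS was called lower without HS 1 (-0.0091, 0.00915). In the other direction, the set higher in HS had a median of -0.042 without control 1 (camera p from genes as a set 0.0546). The set lower in HS had one of 0.23 without control 3 (0.110). Without control 3, the 20 genes then called in HS vs control took the place of these sets and of the 200.

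**Figure D3:**
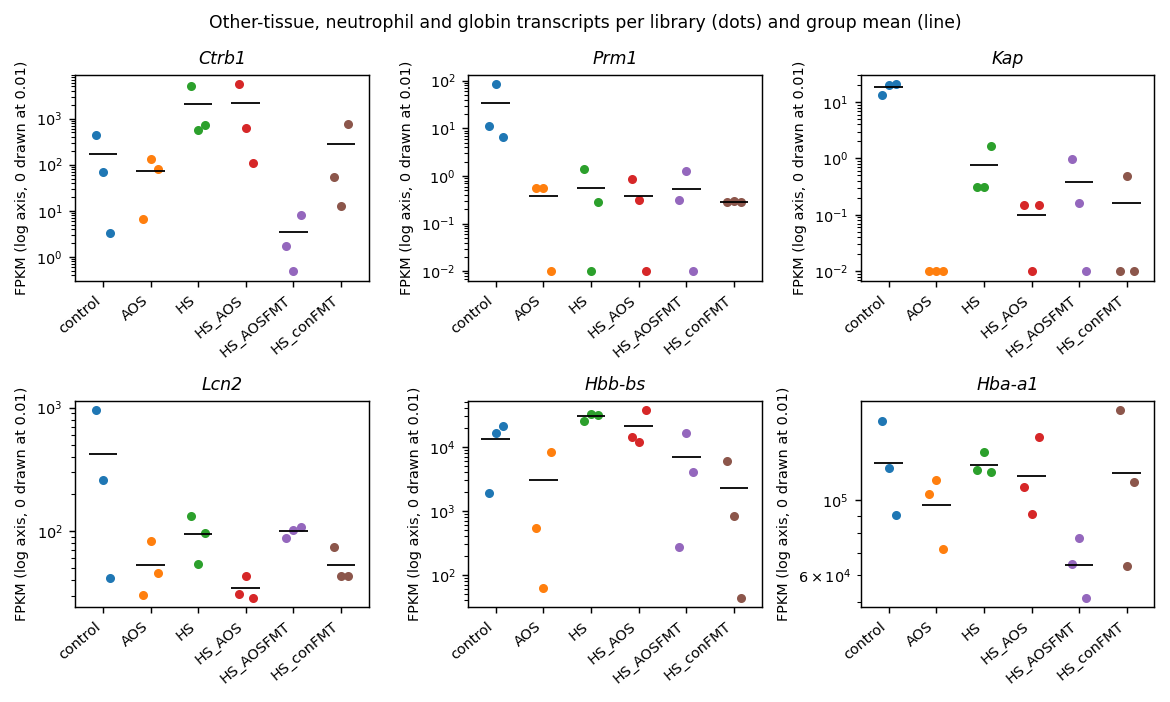
FPKM on a log axis (0 drawn at 0.01) of 6 transcripts that mark another tissue, neutrophils or haemoglobin, with a dot per library and a line at the group mean. The pancreatic gene Ctrb1 had its lowest mean in HS_AOSFMT (3.50 ± 4.15), Prm1 and Kap were highest in the 3 controls, and Hbb-bs spread 850-fold over the 18 libraries against 3.61-fold for Hba-a1.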

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

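The tests of testis RNA below, and the sum of 19 kidney genes, were chosen only after the result was seen. The results here were picked out because the change with AOS under high fat diet and STZ differed from the change with AOS without them, by the interaction test. Kap had a fitted interaction of 3.63 (adjusted p = 0.00195), a value that depends on the pseudocount because Kap was listed at 0 in the 3 AOS libraries. It was called in each fit that left out 1 library, but not with a pseudocount of 0.1. Among 100 splits of the 12 libraries 12 gave as many genes as the 1 called, and the highest other count was 1, so chance was not excluded for that count.

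Of the 31 lists, 15 had an interaction by camera at its preset correlation, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. Plasma cell markers had a median of -1.06 (0 of 12 positive, adjusted p = 1.42e-18; adjusted p = 0.0748 with an estimated correlation), since they rose with AOS alone and were lower in HS_AOS than in HS. For unfolded protein response genes it was -0.66 (2 of 16 positive, adjusted p = 3.59e-16; adjusted p = 0.0748 with an estimated correlation); fry called those 2 lists (adjusted p = 0.0207 and 0.0160). Medians below 0 were also found for germinal centre B cell genes (-0.71), interferon response genes (-0.65), heat shock genes (-0.56), T cell markers (-0.41), macrophage markers (-0.28), glycolysis genes (-0.24), inflammatory cytokine and NF-kB genes (-0.22), ribosomal protein genes (-0.12), oxidative phosphorylation genes (-0.10) and p53 target genes (-0.078). Medians above 0 were those of neutrophil and granule genes (0.79), erythroid genes (0.53) and endothelial markers (0.17), and these 13 lists had adjusted p of 0.598 to 0.722 with an estimated correlation.

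Kap and the sperm genes Prm1 and Tnp1 were high in the 3 controls alone, which shapes the largest falls against control. For the sperm genes, a trace of testis RNA or reads is a candidate source: 90.9% of 22 germ cell genes were higher in control 2 than in all 15 libraries of the other groups. The tables argue against the same source for Kap, whose ratio of control 2 to control 3 was 0.957 against 11.4 to 21.9 for the Prm and Tnp genes, although the lowest ratio among 15 germ cell genes (0.961) lay close to it. Kidney RNA stays open for Kap. The sum of a list of 20 kidney genes (exact permutation p = 0.156) decides nothing, because 1 gene, Napsa, made up 105 of its 110 FPKM in the controls and 132 of its 136 in the others. The other 19 summed to 5.59 ± 0.775 in the controls and 3.94 ± 0.797 in the others (exact permutation p = 0.00613). That difference goes with kidney RNA, but it too leans on 1 gene, Acmsd, at 2.80 in the controls and 1.94 in the others. The rest lie near the floor. Of the 19 genes, 14 were higher in the controls and 4 lower. Biology, such as the absence of AOS, diet and STZ in the controls, also stays open and was not tested.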

How the results depend on the processing

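The covariate fits, with or without beta-globin genes, the fits without HS 1, HS_AOS 1 and control 1, the block within 2 groups, the contrasts of treated groups against control and the leave-one-out tests of the lists were chosen only after the results were seen. Named genes were not followed singly with the covariates or with 3 libraries set aside, beyond what the counts of called genes show for Dbp. Over the other alternatives, 1535 of their results kept direction and side of the threshold, 34 lost their call, 22 gained one and 0 reversed; over leave-one-out the numbers were 1498, 256, 34 and 0. Of the list results, 415 stayed, 54 lost their call (45 of them with an estimated correlation) and 2 reversed, against 321, 10 and 5 over leave-one-out. Where 1 group kept only 2 libraries, its spread was taken from all groups. Absolute depth was not estimated, so what it limits was not tested. Except where fewer libraries or more genes were tested, the cause was not tested for any change below. Camera with an estimated correlation called 1 of 186 list tests instead of 81.

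Quantile normalization gave 794 genes in HS_AOSFMT vs HS, 4 in HS_conFMT vs HS, 8 in HS_conFMT vs control and 143 in the HS groups vs the others, and a reversal median of -0.11 in HS_AOSFMT. limma without trend and robust gave 4 in HS_conFMT vs HS and 2 in AOS vs control. Without a filter the counts were 8 in HS vs control, 2 in HS_conFMT vs HS, 7 in AOS vs control and 16 in HS_conFMT vs control. The reversal medians were then -0.057, -0.076 and -0.064 in HS_AOS, HS_AOSFMT and HS_conFMT. A pseudocount of 0.1 gave 1 in HS vs control, 2 in AOS vs control and 0 for the interaction by limma, and a reversal of -0.17 in HS_AOSFMT.

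Fits to the groups of the contrast alone gave 0 genes in HS vs control by limma (448 unadjusted), 1 in HS_AOS vs HS, 0 in HS_conFMT vs HS (704 unadjusted), 176 in HS_AOSFMT vs HS_conFMT, and 5, 174 and 2 in HS_AOS, HS_AOSFMT and HS_conFMT vs control. Reversal in HS_AOSFMT was then -0.12. A block on replicate number gave 0 by limma in HS_conFMT vs HS (949 unadjusted), 7 in HS_AOS vs control, 9 in HS_conFMT vs control and 116 in the HS groups vs the others. With the block, reversal in HS_AOSFMT was -0.12, and the set of genes higher in HS was called in the donor contrast (median 0.15, camera p from genes as a set 0.0203). Read as pairing within 2 groups, the block gave 1 in HS_AOS vs HS.

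The erythroid level as a covariate gave 83 in HS_AOSFMT vs HS (352 without beta-globin genes in that level), 0 by limma in HS_conFMT vs HS (937 unadjusted), 1184 in HS_AOSFMT vs HS_conFMT, 186 and 2 in HS_AOSFMT and HS_conFMT vs control, and 236 in the HS groups vs the others. The acinar level gave 18, 335, 20 and 699 in HS_AOSFMT vs HS, HS_AOSFMT vs HS_conFMT, HS_AOS vs control and HS_AOSFMT vs control, and 150 in the HS groups. Reversal was then -0.085, -0.36 and -0.20 in HS_AOS, HS_AOSFMT and HS_conFMT. In the donor contrast the set of genes higher in HS changed sign (-0.011) and the set lower in HS was called (0.24, camera p from genes as a set 3.65e-07). Cell division genes in HS_AOSFMT vs HS changed sign with the erythroid (0.22) and acinar (0.052) levels.

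With 3 libraries set aside, the counts were 4 in HS vs control, 5 in HS_AOS vs HS, 388 in HS_AOSFMT vs HS, 0 by limma in HS_conFMT vs HS (896 unadjusted), 7, 439 and 2 in HS_AOS, HS_AOSFMT and HS_conFMT vs control, and 37 in the HS groups. Reversal was -0.26, -0.22 and -0.30 in HS_AOS, HS_AOSFMT and HS_conFMT. The set of genes higher in HS was called in the donor contrast (0.18, camera p from genes as a set 7.04e-05), and the set lower in HS changed sign (-0.021).

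Leaving out 1 library at a time, the counts ran from 3 to 20 in HS vs control, 0 to 3 in HS_AOS vs HS, 203 to 751 in HS_AOSFMT vs HS, 0 to 0 in HS_conFMT vs HS, 199 to 1201 in HS_AOSFMT vs HS_conFMT, 1 to 49 in AOS vs control and 1 to 8 for the interaction. Against control they ran from 2 to 126 in HS_AOS, 448 to 3381 in HS_AOSFMT and 2 to 110 in HS_conFMT, and in the HS groups vs the others from 21 to 499. Called lists numbered 76 to 96. Reversal ran from -0.29 to 0.082, -0.26 to -0.091 and -0.23 to -0.033 in HS_AOS, HS_AOSFMT and HS_conFMT. In the donor contrast the sets of genes higher and lower in HS ran from -0.042 to 0.27 and -0.0091 to 0.23. Lists that changed sign were the acinar genes in HS_AOS vs HS (-2.30 to 0.47), cholesterol synthesis genes in HS_AOSFMT vs HS (-0.12 to 0.021), and erythroid genes in HS_conFMT vs HS (-0.79 to 0.037) and HS_AOSFMT vs HS_conFMT (-0.71 to 0.015). Single genes and libraries behind many of these ranges are named with the results, but not those behind the number of called lists.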

Other observations

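The contrast of the 4 HS groups with AOS and control, the arrangements of whole groups, the erythroid level without beta-globin genes, and the tests of beta-globin haplotypes and erythroid content for the globin genes, were chosen only after the results were seen. Plin2, the lipid droplet coat gene, lay at 30.4 to 48.1 FPKM in the 12 libraries given high fat diet and STZ against 22.2 to 27.0 in the 6 others (log2 change 0.59, adjusted p = 0.00012), and Acot1 at 3.60 to 13.2 against 1.38 to 1.82 (1.5, adjusted p = 0.000781). Pdk4, which turns the cell from glucose to fat (1.19), Cpt1a (0.56), Hilpda, a lipid droplet gene (0.62), and the clock genes Nr1d1 (0.91) and Per1 (0.60) were also called higher. Nr1d1 was not higher in HS itself (3.61 ± 0.283) than in AOS (4.97 ± 1.59), and Hilpda stood at 16.3 ± 1.02 in HS_AOSFMT but 7.98 to 9.13 on average in the other HS groups, near AOS (6.75 ± 1.46). Per1 was highest in HS_AOSFMT (15.8 ± 0.333) and HS_conFMT (13.9 ± 2.95). It stood at 9.47 ± 1.21 in HS and 9.80 ± 0.591 in HS_AOS, against 7.97 ± 0.488 in AOS and 7.20 ± 1.87 in control. Oxct1 (-0.38), Mccc2, of leucine breakdown (-0.39), and Kap (-1.75, although listed at 0 in AOS) were called lower. Mccc2 was lowest in HS_AOSFMT (3.38 ± 0.235) and stood at 6.04 ± 0.348 in HS_conFMT, near control (6.51 ± 0.508), while Oxct1 in HS_AOSFMT (33.1 ± 0.848) lay near control (33.9 ± 1.60). Each of these 10 genes was called without any 1 of the 18 libraries, but Plin2, Acot1, Pdk4 and Cpt1a alone among them had all 12 libraries apart from the 6. Angptl4 (0.70) lost its call without AOS 1 or AOS 2 (highest adjusted p 0.0605), and Acaca, the first enzyme of fat synthesis (-0.38), without AOS 2 (0.0520).

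In the same contrast, cholesterol synthesis genes were lower as a list (median -0.20, 2 of 19 positive, adjusted p = 1.05e-11, and 0.0386 with an estimated correlation). Their mean log2 level was highest in AOS (3.53 to 3.57) and low in HS_AOSFMT (3.20 to 3.22), while HS, HS_AOS and HS_conFMT overlapped control (3.37 to 3.49). Glucocorticoid responsive genes were higher (median 0.33, 12 of 13 positive, adjusted p = 5.11e-10, and 0.00818 with an estimated correlation). That rise lay mostly in HS_AOSFMT: against control the medians of the glucocorticoid list were 1.03 in HS_AOSFMT (adjusted p = 3.93e-08; adjusted p = 0.0229 with an estimated correlation) and 0.28 in HS_conFMT (adjusted p = 0.000294; adjusted p = 0.243 with an estimated correlation), but 0.12 in HS and 0.20 in HS_AOS, both uncalled (0.0876 and 0.103). Fatty acid oxidation and PPAR target genes were higher (median 0.098, 16 of 20 positive, adjusted p = 4.37e-08; adjusted p = 0.266 with an estimated correlation), with 6 called, and adipocyte genes lower (median -0.66, 1 of 12 positive, adjusted p = 0.000302; adjusted p = 0.485 with an estimated correlation). Camera called 17 further lists, 8 up and 9 down, with medians from -0.56 (neutrophil and granule genes) to 1.33 (pancreatic acinar genes), and 2 of the 31 lists were called with an estimated correlation. Leave-one-out was not run on the lists of this contrast. limma called 69 genes, 51 higher and 18 lower, and 1809 had an unadjusted p under 0.05. Among 100 draws of the labels over single libraries 1 gave as many, the real draw itself, and the highest other count was 64. Those draws split up the groups, and the contrast was chosen after the results were seen, so they do not exclude chance. Arrangements of whole groups did not exclude it either: of the 15 ways to set 2 of the 6 groups against the other 4, 6 gave as many. The other 5 all set HS_AOSFMT apart, with 999 the highest, so the count alone does not point to diet and STZ. The count was 27 and 39 without HS 2 and HS 3, 29 and 35 without HS_AOS 1 and 2, 36, 34 and 25 without HS_AOSFMT 1, 2 and 3, 32 without HS_conFMT 3, 22, 21 and 26 without AOS 1, 2 and 3, and 38, 40 and 499 without control 1, 2 and 3, with 18 genes called in every fit.

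The 3 libraries against 3 in the other contrasts make 10 splits, too few for a share under 0.05. HS vs control called 2 genes, and 2 of 10 splits gave as many. The highest other gave 545, with HS 1, control 1 and control 2 on the same side, which points to a structure of the samples other than the groups. HS_AOS vs HS called 0 by limma (674 unadjusted), as many as 10 of 10 splits, with 1 the highest other. HS_AOSFMT vs HS called 1197 (1 of 10; highest other 0), HS_AOSFMT vs HS_conFMT 759 (1 of 10; 0), AOS vs control 1 (1 of 10; 0) and HS_conFMT vs HS 1 (2 of 10; 1). Against control, HS_AOS called 12 (1 of 10; 0), HS_AOSFMT 1558 (1 of 10; 12) and HS_conFMT 5 (2 of 10; 1183). That last split put HS_conFMT 1, control 1 and control 2 together, which also points to a structure of the samples. The reversal medians of -0.12, -0.15 and -0.13 in HS_AOS, HS_AOSFMT and HS_conFMT were matched by 6, 7 and 7 of 10 splits, with the furthest others at -0.20, -0.27 and -0.25.

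The wide response of HS_AOSFMT against HS was weighed against 4 technical sources on the median size of its called changes (0.43). The tables argue against a gene length and GC trend (0.929 of the size kept after correction, 1000 called) and the scaling of the deposited values (0.845, 794 called) as the whole cause. With the acinar level as a covariate, 0.784 was kept (0.770 to 0.810 without any 1 library). That fit cannot decide how much less acinar RNA accounts for, because the mean log2 acinar level almost followed the contrast. It was 5.61 to 8.46 in HS and 0.458 to 1.52 in HS_AOSFMT. The falls of the acinar genes themselves need not be changes of the spleen: pancreas taken with it, or reads of other samples, stay open as their source and were not told apart. With the acinar covariate 18 genes were called, because the median size fell to 0.34 while the median SE rose from 0.10 to 0.15. A lower share of erythroid RNA stays open as a candidate source of part of it, with 0.687 of the size kept (0.561 to 0.717 without any 1 library), 83 called and a median SE of 0.11. That level includes the beta-globin genes, which varied apart from red cell content; without them 0.726 was kept (0.653 to 0.773 without any 1 library), with 352 called. The transplant itself stays open too, as do the day and hour of collection, which the labels do not give and which cannot be told apart from the groups.

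Adult beta-globin genes varied between libraries apart from red cell content. Hbb-bs spread 850-fold and Hba-a1 3.61-fold, and the SD of log2(Hbb-bs/Hba-a1) was 5.95 times that of log2(Hba-a1), which argues against erythroid content as the source. Hbb-bs and Hbb-bt kept a nearly fixed ratio (SD 0.22) while Hbb-bs against Hbb-b1 varied (SD 3.37), a quotient of 0.0643, and Hbb-b2 followed Hbb-b1 (SD 0.051). A candidate explanation is that beta-globin haplotypes segregate among these outbred mice, but these ratios show only that each pair of genes varied as a unit. The share of Hbb-bs and Hbb-bt was 39.1% to 47.5% in HS, 22.4% to 45.8% in HS_AOS, 0.853% to 43.3% in HS_AOSFMT, 0.0740% to 7.05% in HS_conFMT, 0.111% to 20.6% in AOS and 2.04% to 47.3% in control. The share was thus uneven across the groups, and no genotype was measured. Haplotypes of single mice would give a few separate levels of that share. In-between shares, such as 7.05% in HS_conFMT 1, 14.7% in HS_AOSFMT 3 and 20.6% in AOS 3, argue against haplotypes of single mice as the whole source. The labels do not state explicitly that the libraries of a group come from separate animals.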
